A study of Drosophila melanogaster with 2 samples.

How the data were processed

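The assay was chromatin immunoprecipitation followed by sequencing in whole adult Drosophila melanogaster of pooled sex. The line stably expressed Crg-1 with a C-terminal GFP, and the antibody recognised GFP, per the labels. Chromatin was sonicated to a size range of 200 to 800 bp, per the labels. The 2 libraries carry separate biosample labels and the biological replicate numbers 2 and 3, and they form 1 group. They share a donor label, and whether this means more than the same strain is not given in the sources used here.

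Per the deposited descriptions of the files, the authors called each replicate list from the alignments of that replicate together with 1 control alignment, which both replicates shared, and called the pooled list from both alignments and the same control. The thresholded set was derived by the authors from both replicate lists and the pooled list by irreproducible discovery rate (IDR), a measure based on how ranks hold across replicates. In the lists, the thresholded regions were the 3707 of highest signal in the pooled list. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal column gives the height of each region in the authors' own units, and it served only to rank and filter regions within a list. The deposited column of -log10 q values was read as such from the narrow-peak format and was not used for ranking, because 75.8% of the thresholded regions shared its highest value, 3.75. The p column held -1, for not given, in all lists. The summit offset was taken as deposited.

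The authors deposited lists on 2 builds, dm6 and dm3. The dm6 lists served for all results with coordinates, with the Release 6 genome sequence and Ensembl release 115 annotation, without transposable elements. The dm3 lists served for counts, overlaps, the rank correlation between replicates and arm shares only, since no dm3 annotation was used here and no coordinates were converted. Printed coordinates count from 1. The dm6 replicate and pooled lists held exactly 30000 regions each, down to low signal, so they contain background as well as binding sites. Lists held a few entries with repeated coordinates and different summits, 3 of them in the thresholded set.

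Read depth is not stated in the lists and stays unknown. The 95% Wilson intervals cover counting error over regions only. Regions and genes are not biological replicates, neighbouring regions are not independent, and p-values over them describe these libraries.

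Regions were ranked by signal. Top-ranked regions were the 3707 of highest signal in each replicate, and overlap meant at least 1 bp. Overlap was set against 1000 random placements within the same arm. Ranks were correlated over regions matched 1 to 1. Replicate 2 regions were taken in rank order, each paired with the best-ranked free overlapping region of replicate 3. Thresholded regions were compared with the 25118 pooled-list regions that overlapped none of them, by two-sided Fisher's exact tests. Summits were assigned to the first matching class of promoter (within 500 bp of any start site), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. Intervals of odds ratios used Woolf's method. P-values were adjusted by the Benjamini-Hochberg method within each family of classes, lists or motifs.

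The gene lists were fixed before the data were examined and numbered 15. They were circadian clock, core targets of Clk and cyc, forkhead family, insulin and TOR signalling, ribosomal proteins, heat shock and chaperones, mitochondrial respiratory chain, neurons, photoreceptors, muscle, fat body and yolk, germ line and gonad, gut, glia, and developmental patterning regulators. Of 323 names written out, 12 were matched through an older symbol or another case, and 6 matched no single gene and were not analysed here. Lists were tested against all other protein-coding genes on the 6 arms, and also against 10000 random lists matched on the number of distinct start sites. Named genes were Crg-1, the nearest protein-coding gene to each of the 25 strongest thresholded regions overlapping a top-ranked region in both replicates, the 4 members of each list with the highest signal, and all clock genes with a region.

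Motifs were searched on both strands within 50 bp of the summit, and in a window of the same 101 bp centred 500 bp away on a randomly drawn side, with a two-sided exact McNemar test. A second comparison used 3702 candidate summits that did not pass, matched on GC content in steps of 5 percentage points and on distance to a start site in classes divided at 500 and 5000 bp. Frequencies of all 6-base and 8-base words were compared with the same matched summits.

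Alternatives covered the overlap rule, the number of regions, the build, the promoter distance, the start sites used, the gene assignment, the window size, the background and each replicate alone. For the last, the 3707 top-ranked regions of the other replicate replaced the thresholded set, since an IDR set needs both. The scripts were tested on simulated data. A planted overlap of 70% over 1000 regions was recovered as 70.2%, and a planted odds ratio of 5.47 over 13945 genes as 5.45. A forkhead word planted in 10% of 3707 random windows gave a difference of 5.72 points where 5.72 was expected. The expected odds ratio and difference were computed from the same simulated genes and windows, so they check the arithmetic only. Random sites with no word planted gave -1.35 points where 0 was expected. Of 100 sets of random sites, 6 had an unadjusted p under 0.05 for the forkhead pattern. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.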

Results

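Chromatin from whole adult fruit flies of pooled sex was immunoprecipitated with an antibody against GFP. The flies carried a transgene for Crg-1, a forkhead-family transcription factor first described as a circadianly regulated gene, fused at its C terminus to GFP. The data comprised 1 group with 2 biological replicates, which the labels number 2 and 3. For each replicate the deposited list held 30000 candidate regions on the dm6 build, a further list of 30000 regions came from both replicates pooled, and a thresholded set held 3707 regions that passed the authors' test of irreproducible discovery rate. The lists give no read totals, so the depth of each library is unknown, and no untagged control sample was analysed here. With 1 group, the comparisons were between replicates, between passing and other candidate regions, and between gene groups.

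The thresholded regions had a median width of 440 bp and the authors' signal ran from 109.7 to 1889.4, with a median of 161.2. They were the 3707 regions of highest signal in the pooled list, 12.4% of its 30000 entries. Merging regions that overlapped each other left 3478 separate sites. The X chromosome carried 707 regions against 651.9 expected from its length, and arm 3L carried 698 against 778.3. The small 4th chromosome, most of which is heterochromatin-like, carried 18 regions against 37.3 expected, a ratio of 0.482. The distribution over the 6 arms differed from one in proportion to length (chi-square 24.5, 5 degrees of freedom, p = 1.73e-04), although the ratio lay between 0.897 and 1.09 on the 5 large arms.

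The strongest sites were shared by both replicates. The region of highest signal, 1889.4, ranked 1st in both and covered positions 19590436 to 19590817 of arm 3L, with its summit at 19590622, 98 bp from a start site of CG14100. Its summit was centred on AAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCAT. The next lay in an intron, 1032 bp from a start site of CG11050 (arm 2L, 6612520 to 6612897, signal 1518.2), and also held the same rank, 2, in both replicates. A promoter region of mRpL41, which encodes a protein of the mitochondrial ribosome, followed with a signal of 1360.2 (arm 2R, 15217583 to 15217929). Among the 25 strongest regions found in both replicates, 15 had a summit within 500 bp of a start site, 9 lay in introns and 1 in another exon.

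These 25 regions lay nearest to genes of varied function. The forkhead-family founder fkh, a regulator of salivary gland development, had a promoter region with a signal of 1159 on arm 3R from 28585324 to 28585656, ranked 12th in replicate 2 and 10th in replicate 3. The zinc-finger gene cbt (cabut), which links sugar sensing to circadian output, had an intronic region 1349 bp from a start site with a signal of 1146.5 (arm 2L, 480924 to 481278). The phospholipase C gene norpA, required for phototransduction, had an intronic region with a signal of 957.7 (chromosome X, 4324839 to 4325156). The glycolytic gene Gapdh2 had a promoter region with a signal of 1237.5, and the ribosomal protein gene RpS27 had one of 996.9 with its summit 10 bp from a start site. The promoter region of CG5611, with a signal of 1012.3, had the summit sequence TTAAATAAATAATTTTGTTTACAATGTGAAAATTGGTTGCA, which contains TTGTTTACA, a match to the forkhead pattern. The other genes in this set were Ugalt, smash, CG32772, CG1888, Tlk, CG8320, CG16753, Tcs5, eIF6, CG4004, Lk6, Sox14, CG8892, HmgZ, CG13018 and Sptr, with signals between 906.6 and 1358.7.

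The first comparison asked how far the 2 replicates marked the same sites. Of the 3707 top-ranked regions of replicate 2, 2830 overlapped a top-ranked region of replicate 3, or 76.3% (95% Wilson interval 75.0 to 77.7). In the other direction 2841 overlapped, or 76.6% (75.3 to 78.0). Random placement of the replicate 2 regions within their arms gave a mean overlap of 2.20%, and the highest of 1000 placements gave 3.13%. The shared percentage was 86.0 for the 100 strongest regions and 67.1 for the whole replicate 2 list. Of the replicate 2 top regions, 33 overlapped nothing in the whole replicate 3 list, and of the replicate 3 top regions, 23 overlapped nothing in that of replicate 2.

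Over 17530 regions matched 1 to 1 between the whole lists, Spearman's rho of the ranks was 0.694 and Pearson's r was 0.613. Among 4324 matched pairs at thresholded regions rho was 0.767 and r was 0.565, with a median of 27 bp between the summits. These correlations are across regions, which are not independent replicates, and no p was computed. Pairing in rank order favours similar ranks where regions of a list overlap each other, and how much this raised the correlations was not tested. Several pairs could overlap the same thresholded region. Both replicate lists were made by the authors against the same control alignments, and how much of the overlap those share was not tested. All 3707 thresholded regions overlapped some region in both whole replicate lists, and 2812, or 75.9%, overlapped a top-ranked region in both.

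**Figure D1:**
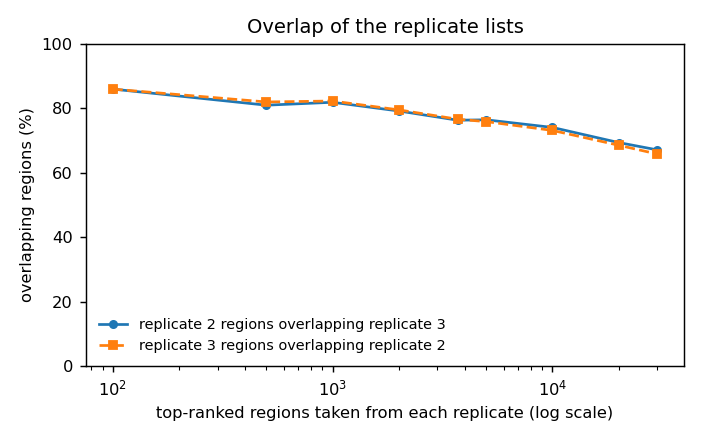
Percentage of the top-ranked regions of each replicate that overlap a top-ranked region of the other by at least 1 bp (vertical axis, %), against the number of regions taken from each list (horizontal axis, log scale). Circles are replicate 2 regions and squares replicate 3 regions; the overlap is 86.0% for the 100 strongest regions and 67.1% for the whole replicate 2 list.

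The regions lay mainly at gene starts. Of the 3707 thresholded summits, 2628 were within 500 bp of an annotated start site, or 70.9% (Wilson interval 69.4 to 72.3). Among the 25118 pooled-list regions that overlapped no thresholded region the share was 30.7% (30.1 to 31.3), an odds ratio of 5.50 (5.09 to 5.93), with a Fisher's exact p too small to be held as a number. Random placement within the arms gave a mean of 13.6% and at most 15.5%. The share fell along the pooled list without a step at the threshold, from 77.1% of the 1000 strongest regions to 62.6% of those ranked 3001 to 4000 and 21.3% of the last 1000.

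Of all summits, introns held 21.5% of thresholded regions and 41.5% of the other candidates (odds ratio 0.385, adjusted p = 2.03e-129 by Fisher's exact test). Intergenic sequence held 4.91% against 10.2% (odds ratio 0.454). Promoters were assigned first, so their larger share lowers the shares of these classes. Of the 1079 thresholded summits away from start sites, 796 were intronic and 182 intergenic. The 25118 other candidates had 10435 and 2573, with 7712 at promoters. These odds ratios therefore do not show depletion of either class away from start sites, which was not tested. Coding exons held 13 thresholded summits, 0.351%, against 10.3% of the other candidates (odds ratio 0.0317, 95% interval 0.0185 to 0.0541). The 3' UTR share was 0.782% against 4.93% (odds ratio 0.155). The classes of 5' UTR and other exons did not pass the threshold (adjusted p = 0.117 and 0.0552 by Fisher's exact test). Under other settings the 5' UTR share of all summits passed as lower with promoters of 1000 bp (adjusted p = 0.0213 by Fisher's exact test). It also passed among the regions of higher signal (odds ratio 0.425, adjusted p = 0.00276 by Fisher's exact test). In replicate 2 alone it passed too (adjusted p = 0.0119 by Fisher's exact test). The share of other exons passed with start sites of protein-coding genes only (adjusted p = 0.00888 by Fisher's exact test). Both shares are also lowered by the larger promoter share. In the main setting 5' UTRs held 37 thresholded summits against 332 other candidates, and other exons 22 against 230. These calls therefore do not show depletion away from start sites, which was not tested. Against random placements the 5' UTR odds ratio lay above 1, at 1.39 (adjusted p = 0.0891 by Fisher's exact test). The comparison ranks candidates by signal within a list, so it describes where the signal was highest and not where binding was absent.

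**Figure D2:**
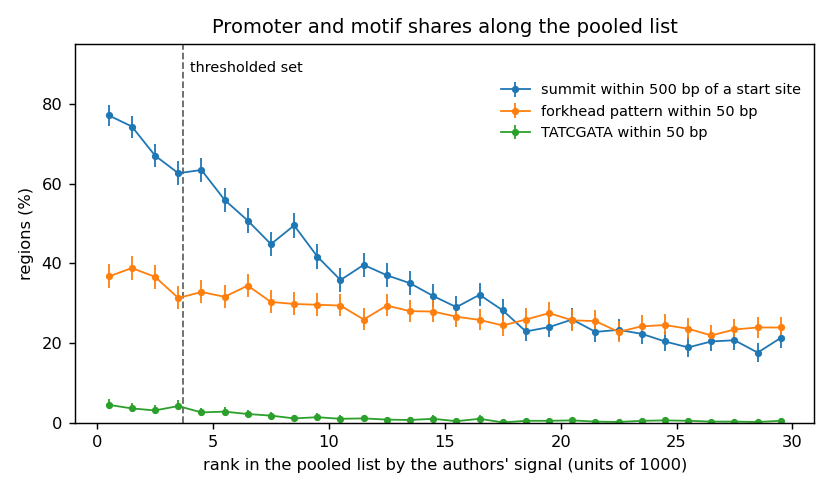
Regions of the pooled list in bins of 1000 by rank of the authors' signal (horizontal axis, in units of 1000) and the percentage in each bin (vertical axis) with a summit within 500 bp of a start site, with a forkhead pattern within 50 bp of the summit, or with TATCGATA within 50 bp. Bars are 95% Wilson intervals and the dashed line marks the 3707 thresholded regions; the start-site share falls from 77.1% to 21.3%.

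The next comparison asked which genes carried a region at the promoter. A thresholded summit lay within 500 bp of a start site in 3195 of 13945 protein-coding genes, or 22.9%. A summit counted for every gene with a start site in reach, so these genes outnumber the 2628 summits near start sites. Genes that share a region are not independent in the tests below. Of 15 gene lists, 4 differed from all other protein-coding genes after Benjamini-Hochberg adjustment of Fisher's exact test. The ribosomal proteins, circadian clock genes and respiratory chain genes had more regions, and the developmental patterning regulators had fewer.

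Genes of the cytoplasmic ribosome stood out most. Of 93 ribosomal protein genes 71 carried a promoter region, or 76.3%, against 22.6% of other genes (odds ratio 10.9, 95% interval 6.78 to 17.6, adjusted p = 1.45e-26 by Fisher's exact test). The highest signals were at RpS27 with 996.9, RpL7 with 861.9 (arm 2L, 10200897 to 10201163), RpS10b with 697.8 and RpL24 with 629.3. The summits of these 4 lay between 10 and 45 bp from a start site. The other 22 members had none.

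Of 24 matched circadian clock genes 14 carried a promoter region, or 58.3%, against 22.9% of other genes (odds ratio 4.66, 2.11 to 10.3, adjusted p = 9.74e-04 by Fisher's exact test). The highest signals were at mts, 480.6, and tws, 451.6, which encode subunits of protein phosphatase 2A. The photoreceptor gene cry followed with 345.9 (arm 3R, 19211785 to 19211954), then the ubiquitin ligase gene slmb with 310.1. Of the core feedback loop, vri had a region with a signal of 168.4, Pdp1 one of 118.5 and tim one of 111.4, near the lowest signal of the set. The tim region ranked 3246 in replicate 2 and 5598 in replicate 3, in the latter outside the 3707 top-ranked regions. Regions were also present at Fbxl4, Atx2, CkIIbeta, sgg, lark, tyf and dco, whereas per, Clk, cyc, cwo, Pdf, Pdfr, jet, nmo, to and CkIIalpha had none at the promoter.

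Several of these genes act in many cell types, and the list was also tested against other backgrounds and in part. Against random lists matched on the number of start sites, 14 genes compared with a mean of 7.93 (odds ratio 2.71, adjusted p = 0.0488 by permutation). In tests chosen after the data were seen, the odds ratio was 2.93 (1.21 to 7.09, adjusted p = 0.0703 by Fisher's exact test) among genes with any pooled-list summit at the promoter. Without 10 kinase, phosphatase, ligase and RNA-binding genes of general function, 6 of 14 genes carried a region, or 42.9% (odds ratio 2.58, 0.927 to 7.16, unadjusted p = 0.105 by Fisher's exact test). The direct targets of the clock activators Clk and cyc, 5 genes that are all in the clock list, had regions at 3 (odds ratio 4.71, 0.9295 to 23.9, adjusted p = 0.176 by Fisher's exact test). For these targets the odds ratio was 8.74 within 1000 bp (adjusted p = 0.0510) and 7.87 with gene bodies (adjusted p = 0.0680, both by Fisher's exact test). Under the other alternatives it lay between 2.10 and 3.53, and none passed the threshold.

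In the mitochondrial respiratory chain 32 of 92 genes carried a region, or 34.8% (odds ratio 1.82, 1.18 to 2.79, adjusted p = 0.0329 by Fisher's exact test). The list was built mainly from symbol prefixes, so it includes like-named genes such as SdhAL, COX4L, ND-49L and ATPsynbetaL. None of these like-named genes had a region, and the list without them was not tested. The strongest were at the complex I genes ND-B22, 372.7, and ND-42, 372.2, then at blw, 326.1, and COX6B, 305.9. This call was lost with the top regions of replicate 3 alone (odds ratio 1.70, adjusted p = 0.0878) and of replicate 2 alone (1.60, adjusted p = 0.113, both by Fisher's exact test). It was also lost against lists matched on start sites (odds ratio 1.68, adjusted p = 0.0606 by permutation), with summits anywhere in the gene body (1.55, adjusted p = 0.118) and among the regions of higher signal (odds ratio 1.36, adjusted p = 0.539, both by Fisher's exact test). Among genes with any pooled-list summit, chosen after the data were seen, the odds ratio was 1.43 (adjusted p = 0.412 by Fisher's exact test). Of the alternatives tried, only the promoter distance of 1000 bp kept the call (1.80, adjusted p = 0.0303 by Fisher's exact test).

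Regulators of developmental patterning, which act in the embryo and in imaginal discs, had few promoter regions in these adult flies. Of 46 such genes 1 carried a region, or 2.17% (odds ratio 0.111, 0.0217 to 0.562, adjusted p = 9.74e-04 by Fisher's exact test). The depletion was weaker with the top regions of replicate 3 alone (odds ratio 0.278, adjusted p = 0.0354) and of replicate 2 alone (0.192, adjusted p = 0.00612, both by Fisher's exact test). The gene with a region in the thresholded set was ey, which specifies the eye, with a signal of 131.8 on chromosome 4 from 697411 to 697850. The Hox genes of the list, the gap gene Kr and the segment polarity genes wg, hh and en had none.

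The remaining lists did not pass the adjusted threshold. In the forkhead family 3 of 18 genes carried a region, fkh, CHES-1-like with a signal of 323.9 and FoxK with 198.7 (adjusted p = 0.827 by Fisher's exact test). In insulin and TOR signalling it was 7 of 28, led by Pi3K21B with 761.6, the insulin receptor gene InR with 455, Thor with 280 and Pi3K92E with 150.6 (adjusted p = 0.827 by Fisher's exact test). Heat shock genes and chaperones had regions at 9 of 23, led by Hsp83 with 848.2, Hsp27 with 570, Hsc70-5 with 324 and Hsc70-3 with 301.3 (adjusted p = 0.176 by Fisher's exact test). Hsp70Aa, Hsp70Ab, Hsp70Ba, Hsp70Bb and Hsp70Bc had none, and whether reads can be placed singly among these genes was not checked.

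Markers of single tissues lay near or below the share of all genes. Among neuronal genes 2 of 25 carried a region, elav with 547.2 and Syx1A with 137.8 (adjusted p = 0.176 by Fisher's exact test), a depletion that passed only against lists matched on start sites (adjusted p = 0.0110 by permutation). The gut list had 1 of 22, GATAe with 112.6 (adjusted p = 0.122 by Fisher's exact test), and passed as depleted only in replicate 2 alone (adjusted p = 0.0298 by Fisher's exact test). Photoreceptor genes had 4 of 24, rdgB, Gbeta76C, Galphaq and ey, with signals of 131.8 to 321.4. Muscle had 4 of 25, Mef2, Tm1, SERCA and sqa, with signals of 120.7 to 187.6. Glia had 4 of 16, moody with 612.9 and then Gs2, drpr and loco. The fat body list had 7 of 24, led by the lipid gene Lpin with 580.3, FASN1 with 248, bmm with 210 and Desat1 with 154.9. The germ line list had 7 of 29, led by Cp36 with 266.1, orb with 218.2, tud with 202.4 and spn-E with 182.3. The region at spn-E was also the one counted for the respiratory chain gene ND-23. For these 5 lists the adjusted p by Fisher's exact test lay between 0.779 and 0.827.

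**Figure D3:**
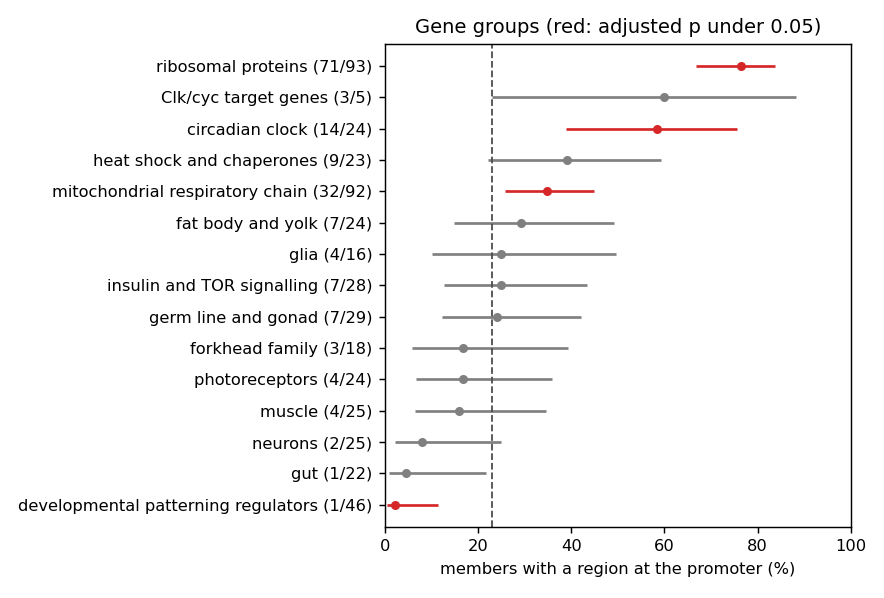
Percentage of the members of each gene list with a thresholded summit within 500 bp of a start site (horizontal axis, %), with counts beside the names. Points are shares, bars 95% Wilson intervals, red marks lists with an adjusted p under 0.05 and the dashed line is the 22.9% of all protein-coding genes; ribosomal proteins reach 76.3% and patterning regulators 2.17%.

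The forkhead recognition pattern RYAAAYA was more frequent at the summits than beside them. It occurred within 50 bp of the summit in 1339 of 3707 regions, or 36.1%, and in 23.5% of windows of the same length centred 500 bp away, a difference of 12.6 percentage points (95% interval 10.5 to 14.7, adjusted p = 2.74e-31 by an exact McNemar test). The reversed pattern AYAAAYR, a control fixed in advance with the same letters read backwards, rose from 22.2% to 30.2%, by 7.99 points (6.02 to 9.95). Both patterns match the words AYAAAYA, so this rise repeats part of the forkhead rise. With those words left out, a comparison chosen after the data were seen, GYAAAYA rose from 10.01% to 19.05% (9.04 points, 7.47 to 10.6) and its reversal AYAAAYG from 8.50% to 9.95% (1.46 points, 0.150 to 2.76). Against summits of other candidate regions matched on GC content and distance to a start site, the forkhead pattern had an odds ratio of 1.25 (1.13 to 1.38, adjusted p = 3.65e-05 by Fisher's exact test). The reversed pattern had 1.12 (1.01 to 1.23, adjusted p = 0.0979 by Fisher's exact test). A split by distance to a start site was chosen after results were seen. The forkhead odds ratio against matched summits was then 1.08 (0.959 to 1.21) at promoters and 1.75 (1.47 to 2.08) elsewhere.

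Core promoter elements, the GATA pattern and the E-box CAGCTG were also more frequent at the summits than in flanks. TATCGATA, the element bound by the factor DREF at many housekeeping genes, occurred at 143 summits, 3.86%, and in 13 flanks, 0.351% (adjusted p = 4.12e-28 by an exact McNemar test). Its odds ratio against the matched summits was 1.86 (1.41 to 2.46). The M1BP element GGTCACAC was found at 1.94% of summits and 0.351% of flanks, TATAAA at 16.0% and 10.8%, and the GATA pattern WGATAR at 20.2% and 16.6%. For these 3 the difference passed against flanks but not against matched summits (adjusted p between 0.328 and 0.729 by Fisher's exact test). The E-box CAGCTG stood at 6.77% of summits and 4.75% of flanks and kept an odds ratio of 1.61 (1.31 to 1.97) against matched summits. Its difference from flanks was 0.702 points among the regions in the upper part of the set by signal (adjusted p = 0.50 by an exact McNemar test).

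The E-box CACGTG bound by Clk and cyc was no more frequent at summits than in flanks, 1.13% against 1.30% (difference -0.162 points, -0.663 to 0.340). The GAGA repeat, the Zelda word CAGGTA and the AP-1 pattern TGASTCA did not pass either (adjusted p between 0.159 and 1 by an exact McNemar test). GAGAGAG passed, however, within 100 bp of the summit, with the top regions of replicate 3 alone and against the summits that did not pass, and CAGGTA passed as depleted within 100 bp and among the regions of higher signal.

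**Figure D4:**
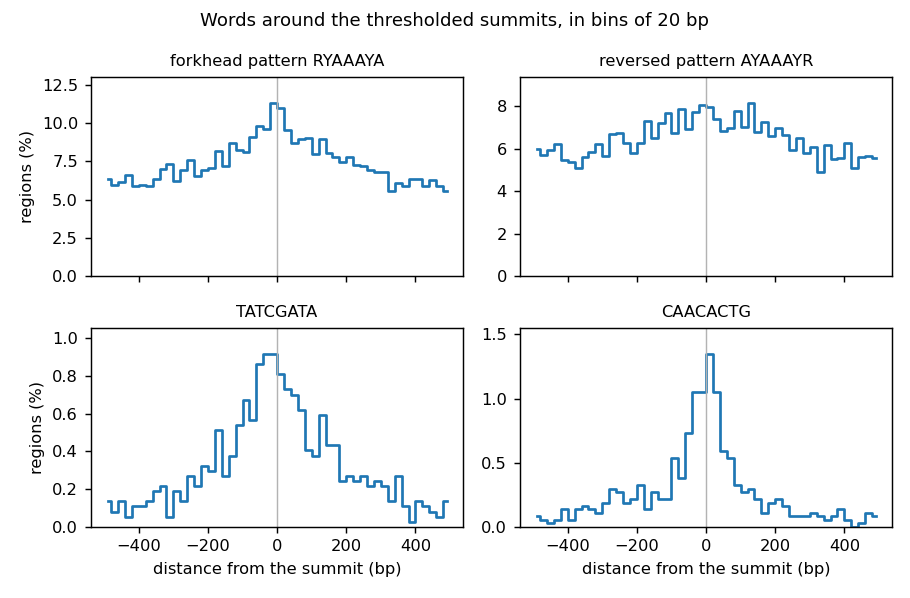
Percentage of the 3707 thresholded regions (vertical axes, %) with a match centred in each bin of 20 bp, by distance from the summit (horizontal axes, bp), for the forkhead pattern, its reversed control (which shares the words AYAAAYA), TATCGATA and CAACACTG, the last chosen after the data were seen. The forkhead pattern reaches 11.3% in the bin before the summit against 6.37% in the bin farthest upstream, and the reversed pattern 8.07% against 5.99%.

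The locus of the tagged gene, with 5 kb on each side, carried no thresholded region. Crg-1 (FBgn0021738) lies on the forward strand of chromosome X from 3793223 to 3797339. In the gene and these flanks the replicate 2 list had 0 regions and the replicate 3 list had 4, the best at rank 16678 with a signal of 18.8. The pooled list had 2, the better at rank 26620 with a signal of 31.8, against a lowest thresholded signal of 109.7. Within 20 kb of the gene there were 3 thresholded regions. The transgene carries an added copy of Crg-1, and reads from it cannot be separated from those of the endogenous locus in these lists.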

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

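The dm3 lists hold regions on sequences named as heterochromatic or unplaced, whereas all regions of the dm6 lists lie on the 6 main arms. No coordinates were converted, so whether the dm6 arms include the same sequence was not checked. The dm3 pooled list had 79 such regions among 27461, of which 27 lay on the sequence Uextra, 18 on XHet and 13 on 2RHet. The replicate 2 list had 85 and the replicate 3 list 64, and 3 of these regions passed into the dm3 thresholded set of 3441, the best at rank 335. They were set apart because the comparisons with coordinates used the dm6 lists alone, and no explanation was tested.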

How the results depend on the processing

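Of 272 values computed under alternative settings, 214 were counted as kept, and 24 changed direction, none of them past the threshold before or after. Tested values counted as kept held their direction and their side of the threshold, and shares and correlations stayed within their error. Counts of regions, classes, lists and motifs only had to stay within a fixed factor of the main count, so 3 gene lists in place of 4 counted as kept. The promoter odds ratio stayed between 4.84 and 15.5 under the 7 alternatives tried, with 5.41 to 5.51 in each replicate alone. Over all regions, the forkhead difference from flanks or backgrounds stayed between 4.97 and 15.4 points and past the threshold under all alternatives tried. In a split chosen after results were seen, it did not pass at promoters against matched summits, 32.3% against 30.7% (adjusted p = 0.409 by Fisher's exact test). The overlap of the top regions moved outside its interval with a larger required overlap (74.6%), with summits within 100 bp (66.9%), with a list shortened to the 1853 strongest (79.7%) and with every region of both lists (67.1%), each of which changes what counts as shared or how many regions can match. The rank correlation was 0.709 with summits within 100 bp. The number of gene lists past the threshold was 4, and 3 with summits in the gene body, with the regions of higher signal and with replicate 3 alone, where the respiratory chain was lost. It was again 4 against lists matched on start sites, where neurons took its place, and 4 with replicate 2 alone, where the gut list did. It was 2 among genes with any pooled-list summit at the promoter, a background chosen after the data were seen, with fewer genes tested. Motifs past the threshold numbered 7 against flanks and 3 against summits matched on GC content and start-site distance, which share the composition of promoters. Without the words that the forkhead pattern and its reversed control share, left out after the data were seen, the number was 6, and the control's difference was 1.46 points (adjusted p = 0.0504 by an exact McNemar test). At the Crg-1 locus the regions within the gene without its flanks numbered 1 in the replicate 3 list and 1 in the pooled list, since fewer bases were searched. The 5' UTR odds ratio went from 0.762 to 1.39 against random placements. For the forkhead family the odds ratio went from 0.759 to 1.07 with gene bodies, 1.425 with regions of higher signal and 2.12 among genes with any pooled-list summit, and for photoreceptors from 0.738 to 1.12, 1.03 and 1.51 with the same changes. Insulin and TOR signalling went from 1.17 to 0.906 against matched lists, 0.865 with regions of higher signal, 0.840 among genes with any pooled-list summit and 0.802 in replicate 2 alone, with 1.44 in replicate 3 alone. The germ line list went from 1.12 to 0.970 at 1000 bp, and glia from 1.21 to 0.943 with gene bodies and 0.843 against matched lists. The CACGTG difference went from -0.162 points to 0.0540 within 100 bp, 0.108 with regions of higher signal, 0.108 against matched summits and 0.297 in replicate 2 alone, with -0.567 in replicate 3 alone. The AP-1 difference went from -0.0270 points to 0.486 with regions of higher signal, 0.243 in replicate 3 alone, 0.0809 in replicate 2 alone, 0.0809 with the opposite flank, chosen after the data were seen, 0.104 against summits that did not pass and 0.243 against matched summits. Single lists, classes and motifs lost a call in 14 cases and gained one in 11, and the causes were not tested. The comparison of the Crg-1 locus on dm3 was not run, because no dm3 annotation was used here. No paired analysis was possible because there was 1 group. The unknown depth limits any statement on weak regions and on regions found in 1 replicate.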

Other observations

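The tests on gene families, on sequence words, on promoter and distal regions apart, on GYAAAYA against AYAAAYG and on the leading word were chosen only after results were seen. The comparison with matched summits over all regions, the Crg-1 neighbourhood and the promoter flanks were set before their values were known.

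Beyond the fixed lists, families of protein-coding genes that share a symbol prefix and have at least 20 members differed widely. Promoter regions were found at 34 of 73 mitochondrial ribosomal protein genes (46.6%, odds ratio 2.96, adjusted p = 3.06e-05 by Fisher's exact test). They were found at 11 of 20 Atg autophagy genes (55.0%, adjusted p = 0.00539 by Fisher's exact test) and 11 of 21 PIG genes for glycolipid anchors (52.4%, adjusted p = 0.00750 by Fisher's exact test). Rab GTPases had 15 of 36, Vps sorting genes 12 of 27 and Vha proton pump genes 11 of 26, with adjusted p from 0.0272 to 0.0484 by Fisher's exact test. By contrast 0 of 70 Cpr cuticle genes, 0 of 59 odorant receptor genes and 0 of 51 odorant-binding protein genes had one, and gustatory and ionotropic receptors had 1 of 60 each (adjusted p at most 1.72e-05 by Fisher's exact test). Cytochrome P450 genes had 7 of 85 (adjusted p = 0.00207 by Fisher's exact test). Histone genes had 3, or 2.61%, but most are near-identical copies in which reads cannot be placed singly. Of other gene types, tRNA genes had a thresholded summit within 500 bp at 23 of 290, or 7.93%, and annotated ncRNA genes at 176 of 3261, or 5.4%.

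Among 20832 words of 8 bases, CAACACTG differed most from matched summits. It lay within 50 bp of 188 of 3702 thresholded summits, 5.08%, and of 24 matched summits, 0.648% (odds ratio 8.05, 5.27 to 12.3, adjusted p = 3.19e-29 by Fisher's exact test). Related words such as CCAACACT, GCAACACT and CAGCACTG followed, with odds ratios of 7.46, 6.23 and 4.68. At promoters the word stood at 6.48% of summits against 0.763%, and at distal regions at 1.67% against 0.371%. The strongest regions with it were at Hsp83, Pi3K21B, CG7006, SRPK and Phs. At Hsp83 (arm 3L, 3192925 to 3193236, signal 848.2) the summit lay 112 bp from a start site. The word was present at 4.0% of the 100 strongest regions (4 of them, 1.57 to 9.84), at 9.25% of regions ranked 101 to 500 and 2.87% of those ranked 2001 to 3707. All 194 occurrences with 10 bases on each side had different surrounding sequences, and the base 4 positions before the word was T in 74.7% of them. Of the 3195 protein-coding genes with a promoter region 255 had the word there (7.98%), with 2 of 71 ribosomal protein genes, 3 of 14 clock genes and 2 of 9 heat shock genes, shares that were not tested. A region in reach of several genes counted for each of them.

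The word was chosen because it differed most from the matched summits, so its odds ratio of 8.05 restates the choice. Chosen again on arms 2L, 2R and X alone, the same word came first, and on arms 3L, 3R and 4, left out of that choice, it stood at 4.83% of thresholded and 0.488% of matched summits. The odds ratio there was 9.80 (4.81 to 19.96), a test added after the word was known. It argues against matched candidate summits carrying the word as often. Those summits had lower signal and were not matched on gene activity, so a word of strong promoters in general cannot be told apart. The choice was then crossed between replicates. The same word came first in the top regions of each replicate on arms 2L, 2R and X, and on the arms left out it had an odds ratio of 8.15 (4.13 to 16.1) in replicate 3 when chosen in replicate 2, and 9.28 (4.55 to 18.9) in replicate 2 when chosen in replicate 3, which argues against a single replicate as its source. No factor was assigned to the word, and what brings it to these summits stays open, because no untagged sample was analysed here.

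The forkhead pattern was examined at promoters and at distal regions apart. GC content as the whole reason for its excess at all summits is argued against by the odds ratio of 1.25 with GC-matched summits. The reversed pattern also lay above 1 there (1.12, 1.01 to 1.23), so the value of 1.25 does not settle composition beyond GC content. The reversed control shares the words AYAAAYA with the pattern, so GYAAAYA was set against AYAAAYG, which have the same bases and no word in common. In promoter regions the forkhead pattern rose by 9.78 points over flanks (7.39 to 12.2), and GYAAAYA by 5.56 points (3.797 to 7.314) against 0.913 for AYAAAYG (-0.571 to 2.40), a difference of 4.64 points (2.40 to 6.89). This difference argues against base composition as the whole reason for the rise over flanks. A rise over flanks was also the outcome set in advance against promoter signal without the pattern. It cannot decide this, because thresholded promoters were not shown to hold the pattern more often than matched candidate promoters that did not pass, 32.3% against 30.7%. The odds ratios against these GC-matched summits were 1.08 (0.959 to 1.21) for the full pattern and 1.06 (0.912 to 1.24) for GYAAAYA, while AYAAAYG had 0.780 (0.650 to 0.935). At the 1079 distal regions the share of the full pattern was 45.2% against 32.1% of matched summits (odds ratio 1.75, 1.47 to 2.08). There the odds ratio of GYAAAYA, 2.22 (1.80 to 2.73), was 1.59 times that of AYAAAYG, 1.39 (1.06 to 1.83), with a bootstrap 95% interval of 1.11 to 2.26, so words of the same bases in another order do not account for the whole excess. The distal odds ratio exceeded that at promoters by a factor of 1.62 (1.31 to 2.00) for the forkhead pattern, but AYAAAYG was also higher at distal regions, so this difference is not confined to forkhead words. Whether Crg-1 or another forkhead protein meets these sites was not tested, and no untagged sample was analysed here.

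Distal regions also held the GAGA repeat at 3.71% of summits against 1.02% of matched summits (odds ratio 3.62, 1.87 to 7.01, adjusted p = 2.58e-04 by Fisher's exact test), but their own flanks held it at 2.78% (difference 0.927 points, -0.548 to 2.40, adjusted p = 0.724 by an exact McNemar test). The GATA pattern stood at 23.5% of distal summits against 18.2% of matched summits (odds ratio 1.39) and 17.9% of their own flanks (adjusted p = 0.00322 by an exact McNemar test).

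Around Crg-1, an added copy of the locus in the transgene could raise the number of regions. Within 20 kb the replicate 2 list had 15 regions, the replicate 3 list 18 and the thresholded set 3, and the pooled list had 17 regions, against a median of 15 and a 95th percentile of 34 around 1000 randomly drawn X-linked genes. The count lay between the bounds set in advance, so an effect of the added copy cannot be told apart from ordinary variation along the chromosome. The size of the transgene insert is not used here, and no biological explanation was tested.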
